A study of Streptomyces venezuelae ATCC 10712 with 8 samples.

How the data were processed

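Total RNA of Streptomyces venezuelae WT and mtrB::apr, grown in liquid medium and sampled at 14 h and 20 h, was depleted of ribosomal RNA and sequenced by the authors in 8 libraries, with 2 biological replicates in each of 4 groups. According to the submitters' processing notes, the authors used Bowtie2 2.2.9, edgeR (version not given) and R 3.3.1. The genome build, the annotation release and the read counter are not given in the sources used here. Libraries are named by group and replicate as the labels give them.

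The authors deposited 1 file per library with RPKM values for 7289 genes. In each file the value times the gene length in kilobases sums to 1000000, so the total is that of the listed genes, and the gene length is the coding length from the deposited gene table. Values times length are whole numbers of bases (within 0.1), and low values pile up at multiples of 75, so the values are sums of base coverage of reads of 75 bases and not read counts. For this reason edgeR and DESeq2, which model counts, were not run. The deposited comparison tables give log2 fold changes, mean log2 CPM, p-values and false discovery rates of the authors' 4 comparisons. In the table for 14 h, 1 row has no gene name, and a cell of the 20 h table holds text where a number belongs. The deposited gene table pairs each identifier (SVEN15_ followed by 4 digits) with its position, strand and product, and 2390 genes are annotated only as hypothetical proteins. None of the 7289 identifiers matched the reference gene table of the species (0 matched), so gene names are those in the product texts.

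The depth per library is given as summed base coverage divided by 75 (4651105 to 7214118 read equivalents). The floor of 3 reads for a gene of 1 kb is 0.416 to 0.645 RPKM. It covers counting error only, since reads without molecular identifiers are not independent molecules. The 10 genes with the highest coverage took 7.9% to 10.1% of the bases. Replicates scattered more than counting allows: the chi-square per degree of freedom over genes with at least 10 read equivalents was 3.03 for WT 14 h (6897 genes), 54.1 for mtrB::apr 14 h (6991), 100 for WT 20 h (7147) and 18 for mtrB::apr 20 h (7086). Within each group no expressed gene held identical values in the 2 replicates (0 genes). Replicate numbers do not pair libraries across groups: the correlations of replicate differences between groups were -0.01, -0.04, -0.01, 0.11, 0.07 and 0.12, so the replicate number is not in the model.

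Genes at 1 RPKM or more in at least 2 libraries were tested (7233 genes). Values as deposited were taken to log2 after adding a pseudocount of 1 RPKM and fitted with limma 3.58.1 (R 4.3.3), with a mean-variance trend and the 4 group means in 1 model of all 8 libraries, so that the groups share an estimate of the spread. The groups did not scatter alike: the median absolute log2 difference between replicates was 0.137 in WT 14 h and 0.425 in WT 20 h. A shared estimate can be too wide for the former and too narrow for the latter. The simulated data below had 1 dispersion and do not check this. Contrasts were mtrB::apr against WT at 14 h and at 20 h, 20 h against 14 h in each strain, and the difference of the mutant effects (20 h minus 14 h). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in a contrast. All tests are two-sided. Principal components were taken from the same log2 values. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. On simulated data with 200 changed genes and a dispersion of 0.054, the fit recovered 95%, 97%, 94% and 98% of changes of 4-fold in the 4 contrasts (51% in the difference) and 26%, 15%, 21% and 27% of changes of 2-fold (7%), and called 6, 11, 8 and 10 (6 in the difference) of 6964 to 6972 unchanged genes.

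The 25 gene lists were fixed by product pattern before the data were examined, as were the contrasts, the filter, the threshold, the rule for named genes and most of the alternative settings. Lists with at least 3 measured genes (24) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The jadomycin list matched no gene. With an inter-gene correlation estimated from the data, none of the list calls of the 4 comparisons of groups held (0 lists in each). So every camera call of a list in the text rests on the preset setting. A higher correlation is not the only reason. The heat shock list had an estimate of -0.00107, under the preset 0.01. Its camera adjusted p still went from 0.0118 to 0.347 in WT with time, and from 0.0321 to 0.406 in the mutant. The values with an estimated correlation thus do not measure the effect of the correlation alone. Fry, which tests a list without the other genes, does not use the preset. By fry, 9 of the 9 lists called at 14 h passed, and 0 of 3 at 20 h. For WT with time 7 of 8 passed, for the mutant with time 6 of 8, and for the difference 6 of 9. Fry was run on values as deposited and does not allow for a shift of all genes. The lists were adjusted after the files were read in these points. The planned locus tags of the chloramphenicol genes could not be paired, so the run SVEN15_0877 to SVEN15_0892 was taken from product texts that name CmlG and PapC, and SVEN15_3971 came in by pattern. The septation list lost 2 para-aminobenzoate synthases (SVEN15_0884 and SVEN15_1109) that the pattern for ParA had matched. Patterns also took in genes that do other things. The TCA list holds SVEN15_5098 and SVEN15_5472, the nitrogen list SVEN15_2341, SVEN15_1136 and SVEN15_6918, and the chaperone list SVEN15_2478, SVEN15_4026, SVEN15_3648, SVEN15_3649 and SVEN15_6563. The translation list holds SVEN15_3180 and SVEN15_0764, and the spore pigment list SVEN15_5851 and SVEN15_5852, which lie away from the run SVEN15_6644 to SVEN15_6651.

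The rule for named genes took mtrA, mtrB, lpqB and the chloramphenicol genes, and per contrast the 10 largest rises and falls among called genes without overlap between libraries, with a mean of 10 RPKM or more in the higher group and an annotated product. It also took the 5 highest and 5 lowest for the difference, and from each list the 4 members with the smallest p, while developmental and septation genes may all be named. A gene outside the rule is said to be chosen after its values were seen. Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of 10 RPKM, median-ratio scaling, quantile normalisation, a block for the replicate number, only the 4 libraries compared, limma without the trend or with robust moderation, a change of 2-fold or more, fry in place of camera, and each library left out in turn. Where a group is left with 1 library, that library is assumed to vary like the other groups. The median-ratio factors were 0.862, 0.871, 0.898, 1.04, 1.1, 1.19, 1.04 and 1.05 in the order WT 14 h, mtrB::apr 14 h, WT 20 h and mtrB::apr 20 h, and under that scaling the median of each called list kept its sign, while medians that moved by over 1.5 times are given beside the result.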

Results

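RNA of Streptomyces venezuelae, a filamentous soil bacterium that sporulates in liquid culture, was sequenced after depletion of ribosomal RNA. The strains were the wild type (WT) and mtrB::apr, in which mtrB, the gene of a membrane sensor kinase, is disrupted. Each strain was sampled at 14 h and 20 h of growth, which gave 4 groups with 2 biological replicates each (8 libraries). MtrB is the partner of the response regulator MtrA. The comparisons ask which transcripts change without the kinase at each time, and how each strain changes from 14 h to 20 h. The files list RPKM values (scaled by gene length and library total) for 7289 genes of a chromosome of 8211324 bases. Summed base coverage per library was 348832839 to 541058819 bases, which corresponds to 4651105 to 7214118 reads of 75 bases. The median gene had 22.61 RPKM in mtrB::apr 14 h replicate 1, the lowest, and 33.02 RPKM in WT 20 h replicate 2, the highest, from 89.7 and 200.3 read equivalents. The value that 3 reads give on a gene of 1 kb was 0.416 to 0.645 RPKM, a floor that covers counting error only. Changes below are log2 fold changes with their standard error (SE) from limma on 7233 genes, and mean RPKM values have the SD of n = 2.

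Replicates differed most at 20 h in WT. The correlation across genes of log2 values between the 2 replicates was 0.993 in WT 14 h, 0.97 in mtrB::apr 14 h, 0.96 in WT 20 h and 0.987 in mtrB::apr 20 h, where genes are not independent replicates. The median absolute log2 difference between replicates was 0.137, 0.405, 0.425 and 0.221 in the same order. The first principal component held 65.5% of the variance and ordered the groups by time and strain. WT 14 h libraries lay at -68.51 and -67.64, mtrB::apr 14 h at -27.03 and -33.94, WT 20 h at 46.15 and 28.03, and mtrB::apr 20 h at 61.88 and 61.05. The second component (16.6%) set the mtrB::apr 14 h libraries (44.21 and 40.8) apart from those of WT 14 h (-28.76 and -29.19).

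The disrupted gene lost nearly all of its signal, while its partner rose. The transcript of mtrB (SVEN15_2695, minus strand, 3006846 to 3008879) had 86.8 ± 6.54 RPKM in WT and 1.21 ± 0.28 RPKM in mtrB::apr at 14 h, a log2 fold change of -5.31 ± 0.27 (adjusted p = 5.27e-06). At 20 h the values were 71.6 ± 11 and 1.24 ± 0.0834 RPKM, a log2 fold change of -5.01 ± 0.27 (adjusted p = 2.3e-05). The pseudocount of 1 RPKM shrinks the change of a gene near that level: with 0.1 RPKM the values for mtrB were -6.06 and -5.73, and the authors' table gives -6.16 and -5.85. The upstream gene mtrA (SVEN15_2696, 3008881 to 3009558), which encodes the response regulator, rose by 1.44 ± 0.23 at 14 h (adjusted p = 0.00257) and by 1.62 ± 0.23 at 20 h (adjusted p = 0.0115). For mtrA the authors' table gives 1.44 and 1.61 (false discovery rates 0.000147 and 0.000157). The call of mtrA at 20 h was lost without either WT 14 h library (adjusted p = 0.0615 each), without mtrB::apr 20 h replicate 1 (0.165) or replicate 2 (0.169), and with only the 4 libraries of that time (0.115). The lipoprotein gene lpqB (SVEN15_2694, 3004994 to 3006856) downstream had a log2 fold change of -0.28 ± 0.23 at 14 h (adjusted p = 0.424) and -0.23 ± 0.23 at 20 h (adjusted p = 0.648). As a list of 3 genes, the mtrA, mtrB and lpqB operon was not called by camera in any of the 4 comparisons (lowest adjusted p 0.349). Members that go different ways leave this test little to find, so it does not speak against the changes of mtrB and mtrA. By fry, which tests a list without the other genes, the adjusted p was 0.00107 at 14 h and 0.00387 at 20 h.

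**Figure D1:**
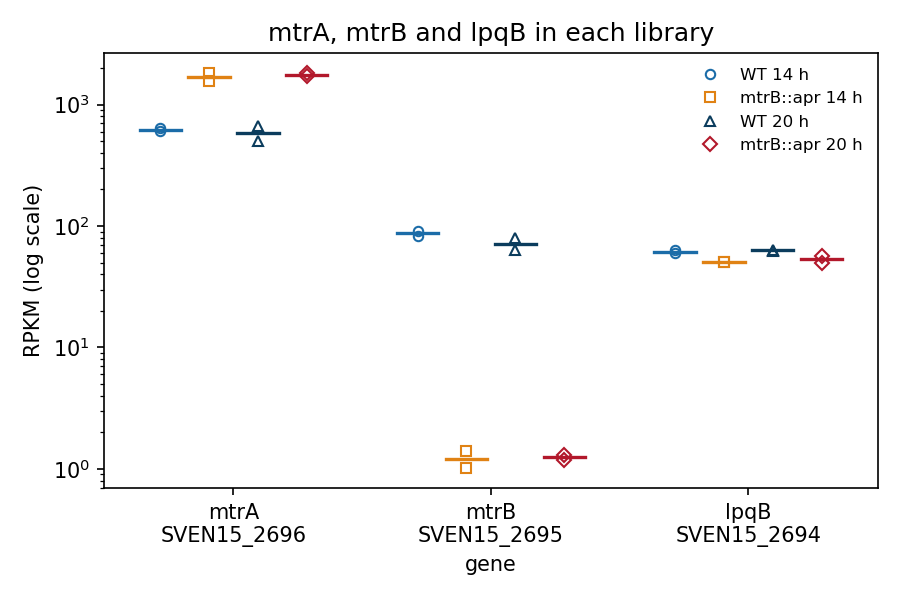
RPKM on a log axis of mtrA, mtrB and lpqB in each of the 4 groups, with a point per library and a bar at the mean of the 2 replicates. In mtrB::apr, mtrB lies at a mean of 1.21 RPKM at 14 h and 1.24 RPKM at 20 h, against 86.8 and 71.6 RPKM in WT.

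At 14 h the mutant carried more transcript for making protein and for respiration than WT, and less of the chloramphenicol, nitrogen assimilation and TCA cycle (tricarboxylic acid cycle) genes. With an estimated correlation, 0 of the 9 lists called at 14 h passed. By fry 9 of the 9 passed (adjusted p = 0.000247 to 0.0169). Of 58 measured ribosomal protein genes, 46 rose and 1 fell (52 and 1 adjusted over the list alone), with a median log2 fold change of 1.42 (camera adjusted p = 4.58e-18; adjusted p = 0.25 with an estimated correlation). For example, ribosomal protein L6p (SVEN15_4297) went from 1980 ± 23.4 to 8800 ± 1680 RPKM, a rise of 2.14 ± 0.23 (adjusted p = 0.000308), and S8p (SVEN15_4296) rose by 2.03 ± 0.23 (adjusted p = 0.000377). The member that fell was L33p (SVEN15_2446, -1.26, adjusted p = 0.0319), chosen after its values were seen. ATP synthase genes rose together, 9 of 10 (10 adjusted over the list alone), by a median of 2.42 (camera adjusted p = 2.4e-08; adjusted p = 0.154 with an estimated correlation). Its B chain gene (SVEN15_4916) went from 305 ± 28.1 to 2030 ± 181 RPKM, and that of the alpha chain (SVEN15_4918) rose by 2.54 ± 0.22 (adjusted p = 6.54e-05). Of the cytochrome oxidase and reductase genes 8 of 10 rose (9 adjusted over the list alone; median 1.34; camera adjusted p = 9.85e-05), among them the iron-sulfur subunit SVEN15_1758 (1.93). Of 25 NADH dehydrogenase genes 10 rose (14 adjusted over the list alone; median 0.87; camera adjusted p = 0.000247), led by chains M (SVEN15_4182, 2.1) and N (SVEN15_4183, 2.33). Both of these lists had an adjusted p = 0.356 with an estimated correlation. Translation factors and tRNA synthetases had 7 of 42 higher and 1 lower (6 and 0 adjusted over the list alone; median 0.38; camera adjusted p = 0.00497; adjusted p = 0.356 with an estimated correlation). Elongation factor G (SVEN15_4276) rose by 1.33 ± 0.22, a call lost without WT 14 h replicate 1 (adjusted p = 0.0514). The lower member was a methylase of release factors (SVEN15_0764, -1.74, adjusted p = 0.0471), chosen after its values were seen. The 3 rodlin genes, whose products coat aerial hyphae and spores, all rose (SVEN15_4528 by 1.45, SVEN15_4531 by 1.57, SVEN15_4532 by 1.33; 3 adjusted over the list alone; camera adjusted p = 0.0249; adjusted p = 0.36 with an estimated correlation). The list was not called without mtrB::apr 14 h replicate 1 (adjusted p = 0.0829). Without a single WT 14 h library the calls of L33p, the methylase and the rodlins were lost (adjusted p = 0.0501 to 0.186). Without mtrB::apr 14 h replicate 1 they were lost too, SVEN15_4531 excepted (adjusted p = 0.0666 to 0.245), and that of the methylase also without either mtrB::apr 20 h library (0.0761 each). The change of SVEN15_4532 was 0.79 without mtrB::apr 14 h replicate 1, and that of the methylase was -1 without it and -2.48 without replicate 2. Other settings ended the call of SVEN15_4532 with median-ratio scaling (0.0541) and with only the 4 libraries compared (0.0588), and that of the methylase with a pseudocount of 0.1 (0.0511), without the trend (0.0506) and with only the 4 libraries (0.0545).

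The lists that were lower at 14 h concerned nitrogen and the TCA cycle, beside the chloramphenicol genes described below. Nitrogen assimilation had 8 of 23 genes lower and 2 higher (the same 8 and 2 adjusted over the list alone; median -0.42; camera adjusted p = 0.00215; adjusted p = 0.308 with an estimated correlation). Glutamine synthetase type I (SVEN15_1812), an enzyme that assimilates ammonium, went from 1860 to 295 RPKM, a log2 fold change of -2.69 ± 0.29 (adjusted p = 0.000303). Genes for urease, which releases ammonium from urea, were lower as well (SVEN15_0801, gamma subunit, -2.97; SVEN15_0797, accessory protein UreG, -2.54). The 2 higher members were a glutamine synthetase family gene (SVEN15_1168, 2.83 ± 0.36) and a glutamate synthase gene (SVEN15_0335, 1.29, adjusted p = 0.0421), the latter chosen after its values were seen. The TCA cycle list had 10 of 23 genes lower and 1 higher (10 and 2 adjusted over the list alone; median -0.33; camera adjusted p = 0.00215; adjusted p = 0.25 with an estimated correlation). Genes of a succinate dehydrogenase fell most (SVEN15_6691 by 4.68 ± 0.63, from 1370 ± 79.8 to 54.7 ± 21.2 RPKM; SVEN15_6690 fell by 4.29 ± 0.73), and a succinyl-CoA ligase gene (SVEN15_4387) fell by 1.42. The higher member, SVEN15_4650 of another succinate dehydrogenase (0.88, adjusted p = 0.0486), was chosen after its values were seen. The calls of SVEN15_0335 and SVEN15_4650 were lost without either WT 14 h library (adjusted p = 0.168 to 0.245), without mtrB::apr 14 h replicate 2 (0.188, with a change of 0.79, and 0.0564), without either mtrB::apr 20 h library (0.0756 to 0.0846) and, for SVEN15_4650, without mtrB::apr 14 h replicate 1 (0.132). Both calls also ended with median-ratio scaling (0.0518 and 0.0907), quantile normalisation (0.0582 and 0.149) and only the 4 libraries compared (0.0623 and 0.0606), and that of SVEN15_4650 with a pseudocount of 5 (0.143). The TCA list was not called without mtrB::apr 14 h replicate 2 (adjusted p = 0.0831).

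Outside the lists, genes are named singly and no group of them was tested. Among genes with an annotated product and 10 RPKM or more, the 10 largest rises at 14 h included neighbours annotated for breakdown of phenylacetate, an aromatic acid. The oxygenase genes SVEN15_3530 to SVEN15_3534 (PaaG, PaaH, PaaI, PaaJ and PaaK) rose by 4.16 ± 0.4, 4.43 ± 0.49, 4.79 ± 0.52, 4.79 ± 0.54 and 5.25 ± 0.56, the last from 13.4 to 645 ± 483 RPKM (adjusted p = 0.000148 to 0.000413). SVEN15_3532, SVEN15_3533 and SVEN15_3534 moved to between 5.51 and 6.1 without mtrB::apr 14 h replicate 1 and between 3.99 and 4.4 without replicate 2. The aldehyde dehydrogenase gene paaZ (SVEN15_3526) rose by 4.71 ± 0.31, from 55.5 to 1540 RPKM (adjusted p = 1.39e-05). A carbonic anhydrase gene (SVEN15_3260) rose by 4.82 ± 0.32, from 6.17 to 203 RPKM. A sugar-binding protein gene of a maltose transporter (SVEN15_1842) rose by 3.97 ± 0.28, from 47.1 to 780 RPKM. Genes annotated as an O-antigen export permease (SVEN15_2678) and a Nudix hydrolase (SVEN15_2190, listed at 0 in a WT 14 h library) rose by 4.32 and 4.09. Among the falls, a reductase gene (SVEN15_5874) went from 336 to 5.79 RPKM, a change of -5.65 ± 0.32 (adjusted p = 8.33e-06), and a permease gene for cytosine or related compounds (SVEN15_0585) fell by 5.1 ± 0.26. Urocanate hydratase (SVEN15_2762) and N-formylglutamate deformylase (SVEN15_2761), enzymes of histidine breakdown, fell by 4.85 ± 0.24 and 5.09 ± 0.36. A thiosulfate sulfurtransferase gene (SVEN15_3830) went from 2500 to 79.7 RPKM (-4.96 ± 0.24) and its neighbour SVEN15_3831, annotated as sseC, fell by 5.04 ± 0.23. Sulfate adenylyltransferase subunit 2 (SVEN15_5794) and adenylylsulfate kinase (SVEN15_5795), which activate sulfate, fell by 4.61 ± 0.29 and 4.53 ± 0.25. Of 7233 genes, 1488 passed an adjusted p of 0.05 at 14 h, 812 higher (54.6%) and 676 lower. With each library scaled by the median ratio, 1481 passed and 40.9% of them were higher, and the median over all genes was 0.02 instead of 0.16. Without WT 14 h replicate 1 or 2 the count was 478 or 487.

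The mutant had far less transcript of the chloramphenicol genes than WT at 14 h, and both strains had little at 20 h. The list holds the 16 neighbouring genes SVEN15_0877 to SVEN15_0892, a run bounded from product names after the files were read, and a chloramphenicol phosphotransferase gene elsewhere (SVEN15_3971). At 14 h, 11 of the 17 fell and none rose (14 fell and SVEN15_0880 rose adjusted over the list alone), with a median log2 fold change of -2.2 (camera adjusted p = 1.01e-09; adjusted p = 0.356 with an estimated correlation). SVEN15_0889, of unknown function, went from 1170 ± 56 to 85 ± 15.6 RPKM, a log2 fold change of -3.77 ± 0.26 (adjusted p = 1.64e-05). Similar falls were measured for CmlG (SVEN15_0887, -3.47 ± 0.46), a dehydrogenase (SVEN15_0890, -3.69 ± 0.31), SVEN15_0888 (-3.15 ± 0.3), a non-ribosomal peptide synthetase (SVEN15_0886, -3.06 ± 0.46) and an FAD-binding protein (SVEN15_0892, -2.78 ± 0.37). For CmlG, SVEN15_0886 and SVEN15_0892 the values were -2.62, -2.22 and -2.13 without mtrB::apr 14 h replicate 1 and -4.33, -3.89 and -3.44 without replicate 2. From 14 h to 20 h in WT, 16 of the 17 fell, with a median of -3.21 (camera adjusted p = 1.78e-14; adjusted p = 0.347 with an estimated correlation), and SVEN15_0889 and CmlG changed by -4.76 ± 0.26 and -4 ± 0.46. In mtrB::apr 11 fell from 14 h to 20 h (13 adjusted over the list alone; median -1.32; camera adjusted p = 7.87e-06; adjusted p = 0.579 with an estimated correlation; fry adjusted p = 0.12), SVEN15_0889 by 1.36 ± 0.26 (adjusted p = 0.00379). At 20 h SVEN15_0889 had 42.4 RPKM in WT and 32.5 RPKM in mtrB::apr (log2 fold change -0.37 ± 0.26, adjusted p = 0.485). Its mutant effect differed between the times by 3.4 ± 0.36 (adjusted p = 0.000728). The transporter gene SVEN15_0880 in the same run went from 18.4 RPKM in WT to 149 RPKM in mtrB::apr at 20 h, a rise of 2.94 ± 0.3 (adjusted p = 0.00183; 0.064 without mtrB::apr 20 h replicate 2). The authors' table gives 3.01 for this rise (false discovery rate 2.3e-12). SVEN15_0880 fell by 2.04 ± 0.3 with time in WT (adjusted p = 0.000751), and changed by 0.14 ± 0.3 with time in the mutant (adjusted p = 0.765). Its change at 14 h was 0.75 ± 0.3 (adjusted p = 0.106; 0.0278 without mtrB::apr 14 h replicate 1). The difference of its mutant effect was 2.19 ± 0.42 (adjusted p = 0.0152), lost without either WT 14 h library (0.0701 and 0.0965) or either mtrB::apr 20 h library (0.0578 and 0.0859). The phosphotransferase gene SVEN15_3971 changed by 0.05 ± 0.24 at 14 h (adjusted p = 0.904), and this value was -0.11 with median-ratio scaling. With time it changed by -0.02 in WT (adjusted p = 0.959) and by -0.85 in the mutant (adjusted p = 0.0285), the last call lost without any 1 of the WT 14 h, mtrB::apr 14 h and mtrB::apr 20 h libraries (adjusted p = 0.0535 to 0.21).

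**Figure D2:**
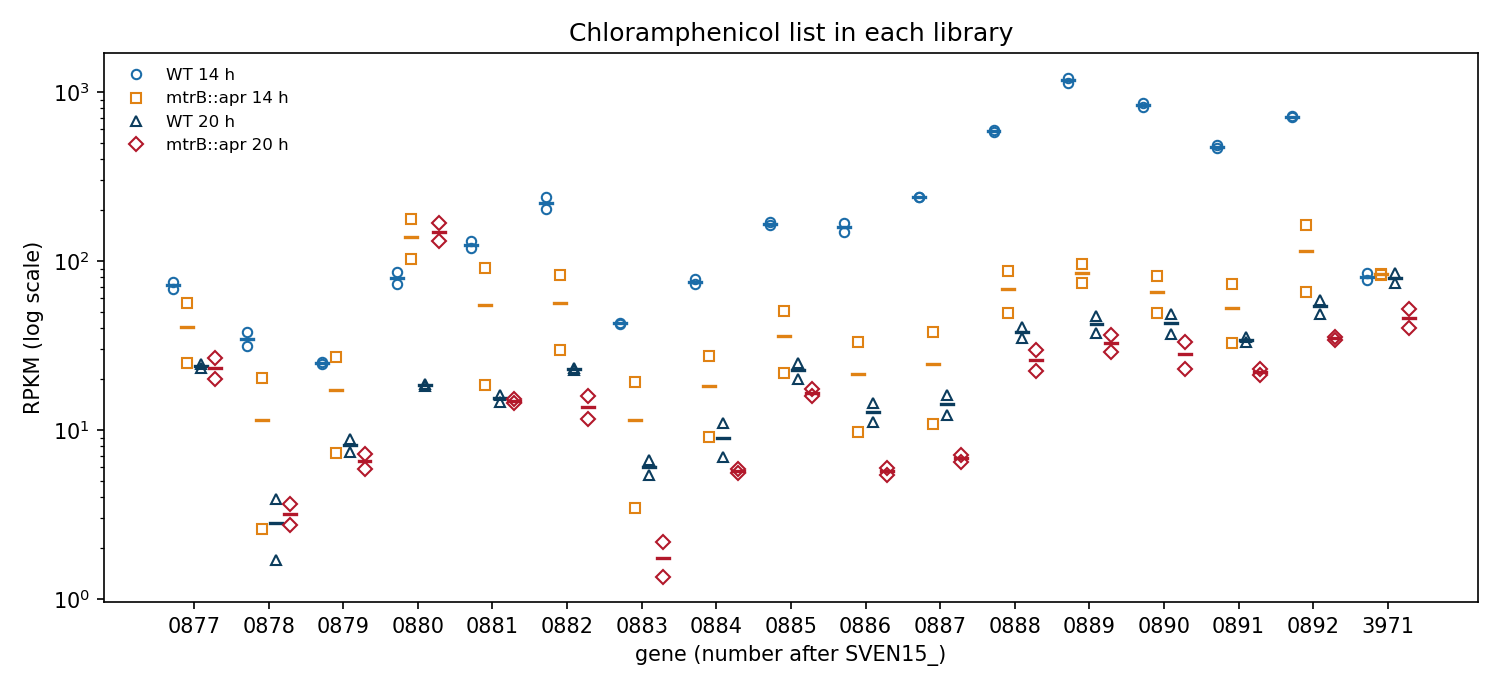
RPKM on a log axis of the 17 genes of the chloramphenicol list in the 4 groups, with a point per library and a bar at the mean of 2 replicates. SVEN15_0889 lies at a mean of 1170 RPKM in WT 14 h and at 85, 42.4 and 32.5 RPKM in mtrB::apr 14 h, WT 20 h and mtrB::apr 20 h.

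At 20 h few single genes were called between the strains (78 of 7233), which need not mean that few differ. In the authors' own comparison at 20 h, 273 genes had a false discovery rate under 0.05. On simulated data the fit recovered 97% of changes of 4-fold in this contrast but 15% of changes of 2-fold. A pyruvate formate-lyase activating enzyme gene (SVEN15_2978) went from 124 ± 40.4 to 1800 ± 2.98 RPKM, a rise of 3.88 ± 0.31 (adjusted p = 0.00036), and its neighbour for pyruvate formate-lyase (SVEN15_2979), chosen after its values were seen, rose by 2.13 ± 0.28 (adjusted p = 0.00845). A run with a beta-mannosidase (SVEN15_6749, 2.72 ± 0.25, from 6.95 to 51.6 RPKM), a sugar-binding lipoprotein (SVEN15_6750, 2.73 ± 0.28) and a LacI family regulator (SVEN15_6748, 2.39 ± 0.3) was higher in the mutant. So were a sodium:dicarboxylate symporter (SVEN15_4980, 2.66 ± 0.26), an ABC transporter ATPase (SVEN15_2467, 2.6 ± 0.35), a regulatory protein (SVEN15_2465, 2.47), a threonine aldolase (SVEN15_0695, 2.61), a hydrolase (SVEN15_1880, 2.24) and 3-isopropylmalate dehydrogenase (SVEN15_5098, 1.66). Lower in the mutant were a branched-chain keto acid dehydrogenase subunit (SVEN15_3521, -4.22 ± 0.82, adjusted p = 0.0493), a sugar-binding secreted protein (SVEN15_6449, -2.1), phosphoglycerate dehydrogenase (SVEN15_5084, -1.81), a prenyl diphosphate synthase (SVEN15_4812, -1.76), an AraC family regulator (SVEN15_2524, -1.76) and porphobilinogen synthase (SVEN15_3109, -1.7). PaaZ (SVEN15_3526, -1.67), an enoyl-CoA hydratase (SVEN15_5009, -1.67) and PaaA (SVEN15_6060, -1.64) were lower too. The neighbouring short genes SVEN15_3350 and SVEN15_3351 of unknown function, chosen after their values were seen, fell at both times, with changes of -5.8 ± 0.34 and -6.22 ± 0.29 at 14 h and -5.49 ± 0.34 and -6.15 ± 0.29 at 20 h. SVEN15_3350 had 7870 ± 428 RPKM in WT and 141 ± 25.7 RPKM in mtrB::apr at 14 h, and 10300 ± 5330 and 213 ± 22.5 RPKM at 20 h.

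Of the genes named for 20 h, mtrB, SVEN15_2978, SVEN15_3350 and SVEN15_3351 passed without each library in turn. The other genes that were higher in the mutant lost their call without mtrB::apr 20 h replicate 2 (adjusted p = 0.0539 to 0.351), and SVEN15_2979, SVEN15_2465, SVEN15_1880, SVEN15_0695 and SVEN15_5098 also without its replicate 1 (0.0851 to 0.333). The genes that were lower, SVEN15_3521, SVEN15_6449, SVEN15_5084, SVEN15_4812, SVEN15_2524, SVEN15_3109, SVEN15_3526, SVEN15_5009 and SVEN15_6060, lost it without either mtrB::apr 20 h library (adjusted p = 0.068 to 0.384). All of these except SVEN15_6449, and SVEN15_2465, SVEN15_1880, SVEN15_0695 and SVEN15_5098 among the higher genes, lost it without either WT 14 h library (adjusted p = 0.0512 to 0.115). SVEN15_1880, SVEN15_0695, SVEN15_3109, SVEN15_5009 and SVEN15_6060 lost it without WT 20 h replicate 2 (adjusted p = 0.0502 to 0.13), SVEN15_0695 without its replicate 1 (0.0524), and SVEN15_2465, SVEN15_3521 and SVEN15_5009 without either mtrB::apr 14 h library (0.0507 to 0.0657). WT replicates moved the changes of SVEN15_3521 (-2.64 without WT 20 h replicate 1, -5.81 without replicate 2) and SVEN15_2465 (1.76 and 3.18). With only the 4 libraries of 20 h, 14 of these calls ended (adjusted p = 0.0528 to 0.158): those of all the lower genes but SVEN15_3350, SVEN15_3351 and mtrB, and those of SVEN15_2467, SVEN15_2465, SVEN15_1880, SVEN15_5098 and SVEN15_2979. A pseudocount of 0.1 ended those of SVEN15_2465, SVEN15_1880, SVEN15_0695, SVEN15_5098, SVEN15_3521, SVEN15_3526 and SVEN15_5009 (0.0508 to 0.0754). A fit without the trend ended those of SVEN15_2465, SVEN15_0695, SVEN15_3521, SVEN15_3526 and SVEN15_5009 (0.0568 to 0.0643). Robust moderation ended those of SVEN15_0695, SVEN15_3521 and SVEN15_5009 (0.0514 to 0.0519), and quantile normalisation those of SVEN15_2465 (0.0765) and SVEN15_5098 (0.055). The call of SVEN15_3521 ended with a pseudocount of 5 (0.0524) and median-ratio scaling (0.0534) too, and that of SVEN15_0695 with no filter on low values (0.0503). In all, 78 of 7233 genes passed at 20 h, 44 higher (56.4%) and 34 lower, and 1236 had an unadjusted p under 0.05. With median-ratio scaling 88 passed, 67% of them higher, and the median over all genes went from -0.09 to 0.03. The count was 682 without WT 20 h replicate 1, 15 or 6 without mtrB::apr 20 h replicate 1 or 2, 27 without either WT 14 h library, 18 with only the 4 libraries of 20 h and 51 with a pseudocount of 0.1.

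Genes for the spore pigment, a polyketide of mature spores, were higher as a group in the mutant at 20 h, although no member passed over all genes. The 10 measured genes had a median log2 fold change of 1.98 (camera adjusted p = 0.000283; adjusted p = 0.942 with an estimated correlation), and 8 were higher adjusted over the list alone. Aromatase WhiE VI (SVEN15_6645) had 271 ± 293 RPKM in WT and 912 ± 87 RPKM in mtrB::apr, a change of 2.37 ± 0.8 (adjusted p = 0.184). Cyclase WhiE II (SVEN15_6649) had 187 ± 189 and 673 ± 118 RPKM, a change of 2.34 ± 0.71 (adjusted p = 0.142). The WT replicates stood apart, with 479 RPKM of SVEN15_6645 in replicate 1 and 64.1 RPKM in replicate 2. The list's median was 0.57 without WT 20 h replicate 2 (adjusted p = 0.0122) and 3.37 without replicate 1 (adjusted p = 5.4e-09), where SVEN15_6645 and SVEN15_6649 passed (adjusted p = 0.00739 and 0.00509). Nitrogen assimilation was lower as a list (median -0.46 over 23 genes; camera adjusted p = 0.0275; adjusted p = 0.942 with an estimated correlation) with no member called, over all genes or over the list alone. The urease alpha subunit (SVEN15_0799) changed by -1.1 ± 0.33 (adjusted p = 0.14) and glutamine synthetase type II (SVEN15_1823) by -2.09 ± 0.58 (adjusted p = 0.126). For SVEN15_1823 the WT replicates stood apart, at 574 and 133 RPKM, against 93.5 and 43.8 RPKM in the mutant. The nitrogen list was not called without WT 20 h replicate 1 or mtrB::apr 20 h replicate 2. Septation and cell division genes were higher as a list (median 0.27 over 25 genes; camera adjusted p = 0.0448; adjusted p = 0.942 with an estimated correlation), also with no member called. Its members with the smallest p included FtsW (SVEN15_2334, 0.77 ± 0.29, adjusted p = 0.22) and MreB (SVEN15_2179, 1.18 ± 0.47, adjusted p = 0.241; 0.00346 without WT 20 h replicate 1). The septation list was not called without either WT 14 h library (adjusted p = 0.0607 each), WT 20 h replicate 2 (0.458) or mtrB::apr 20 h replicate 2 (0.262), with a pseudocount of 5 (0.0505), or with 2 para-aminobenzoate synthases that its search pattern also matched (0.0827). By fry, which asks whether a list moves one way, these lists had adjusted p values of 0.403 (spore pigment), 0.147 (nitrogen) and 0.403 (septation).

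From 14 h to 20 h in WT the lists of spore pigment and rodlin genes rose and the chloramphenicol list fell, but none passed with an estimated correlation (adjusted p = 0.626, 0.626 and 0.347). The rodlin list was also not called without either WT 20 h library (0.0797 and 0.076). The largest changes among single annotated genes are given first, and no group of these was tested. The fructose genes SVEN15_2988, SVEN15_2989 and SVEN15_2990 (transporter, phosphofructokinase and repressor) fell, with changes of -8.3 ± 0.31, -8.67 ± 0.31 and -8.71 ± 0.43, the last from 1340 to 2.22 RPKM. Urocanate hydratase (SVEN15_2762) and histidine ammonia-lyase (SVEN15_4503) fell by 5.13 ± 0.24 and 4.96 ± 0.33, and xylose isomerase (SVEN15_6511) by 5.15 ± 0.23. A phage tail sheath protein (SVEN15_5727) and a Vgr protein (SVEN15_5720) fell by 6.37 ± 0.61 and 5.61 ± 0.76, the reductase SVEN15_5874 by 5.84 ± 0.32 and a quinone oxidoreductase (SVEN15_4202) by 5.56 ± 0.37. A response regulator (SVEN15_6653) rose by 5.26 ± 0.52, a chemotaxis protein (SVEN15_6952) by 4.97 ± 0.47, an arabinose-binding protein (SVEN15_6934) by 4.93 ± 0.43 and a hemolysin (SVEN15_6718) by 4.82 ± 0.38. The Nudix hydrolase SVEN15_2190 (5.07), the maltose-binding protein SVEN15_1842 (4.77) and a phage protein (SVEN15_2094, 4.77) rose as well. WhiD (SVEN15_4354), a regulator of spore maturation, rose by 3.88 ± 0.46, from 70 to 1230 ± 920 RPKM, and a WhiB family regulator (SVEN15_4802) by 1.71 ± 0.23. Their list of developmental regulators had 8 of 14 higher and 1 lower and was not called (camera adjusted p = 0.38). Camera compares a list with all other genes, and by fry, which does not, the adjusted p was 0.00158. Fry was run on values as deposited only, and the list's median of 0.84 was 0.44 with median-ratio scaling. Without WT 20 h replicate 1 the rises were 4.45 for SVEN15_6653, 4.3 for SVEN15_6934, 5.69 for SVEN15_2190 and 3.03 for WhiD, and without replicate 2 they were 6.07, 5.56, 4.46 and 4.73. The count was 2901 of 7233 genes, 2085 higher (71.9%) and 816 lower. With median-ratio scaling it was 2619 and 48% of them higher, and the median over all genes was 0.03 instead of 0.39. Without WT 14 h replicate 1 or 2 it was 1500 or 1553.

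Spore pigment genes rose in WT with time, 8 of 10 (8 adjusted over the list alone; median 3.86; camera adjusted p = 0.0116; adjusted p = 0.626 with an estimated correlation). Acyl carrier protein WhiE V (SVEN15_6646) rose by 4.84 ± 0.76, from 5.63 to 315 ± 357 RPKM, and cyclase WhiE VII (SVEN15_6644) by 4.69 ± 0.7. Gas vesicle genes rose, 8 of 16 (10 adjusted over the list alone; median 1.15; camera adjusted p = 0.0424), with SVEN15_6705 up by 4.51 ± 0.56, SVEN15_6707 by 2.05 and SVEN15_6709 by 2.04. The rises of SVEN15_6646, SVEN15_6644 and SVEN15_6705 were 3.27, 3.25 and 3.7 without WT 20 h replicate 1 and 6.42, 6.13 and 5.31 without replicate 2. The spore pigment median of 3.86 thus rests on WT 20 h replicates that stood apart. The 3 rodlin genes rose (SVEN15_4528 by 2.88 ± 0.31, SVEN15_4531 by 2.23 ± 0.29, SVEN15_4532 by 1.87 ± 0.34; camera adjusted p = 0.0402). So did 8 of 10 cytochrome oxidase and reductase genes (median 1.04, and 0.65 with median-ratio scaling; camera adjusted p = 0.0402). These 3 lists had an adjusted p = 0.626 with an estimated correlation. ATP synthase genes rose, 7 of 10 (median 1.5; camera adjusted p = 0.0118; adjusted p = 0.347 with an estimated correlation), the alpha chain gene SVEN15_4918 by 1.62 ± 0.22. Heat shock and chaperone genes had 6 of 18 lower and 2 higher (6 and 3 adjusted over the list alone; median -0.64, and -1.04 with median-ratio scaling; camera adjusted p = 0.0118; adjusted p = 0.347 with an estimated correlation). GroEL (SVEN15_3957), a chaperone for folding, went from 7670 to 1900 RPKM (-2.02 ± 0.26) and GroES (SVEN15_4342) fell by 1.26 ± 0.28 (adjusted p = 0.00643; 0.058 without WT 14 h replicate 2). The higher members were a copper chaperone (SVEN15_2478, 1.58), which carries metal and is no folding chaperone, and a ribosome-associated protein (SVEN15_0247, 1.64, adjusted p = 0.0117), chosen after its values were seen. The latter was not called without either WT 14 h library (adjusted p = 0.0581 and 0.0627) or WT 20 h replicate 2 (0.0661). TCA cycle genes had 9 of 23 lower and 4 higher (median -0.55, and -0.94 with median-ratio scaling; camera adjusted p = 0.0274; adjusted p = 0.347 with an estimated correlation; fry adjusted p = 0.585). The higher ones were 3 succinate dehydrogenase genes (SVEN15_4649, 2.96; SVEN15_4650, 3.43; SVEN15_4651, 3.82) and 3-isopropylmalate dehydrogenase (SVEN15_5098, 4.49 ± 0.3), an enzyme of leucine synthesis that the search pattern took in. As a list, the oxidases were not called without WT 14 h replicate 1 or 2 or WT 20 h replicate 1 (adjusted p = 0.069, 0.0506 and 0.343), and the gas vesicles without WT 14 h replicate 2 or WT 20 h replicate 1 (0.0506 and 0.199).

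In the mutant the same span of time brought the spore pigment genes up and took ribosomal protein genes down. Of 10 spore pigment genes 8 rose (8 adjusted over the list alone; median 5.94; camera adjusted p = 7.87e-06; adjusted p = 0.493 with an estimated correlation). SVEN15_6645 went from 6.73 to 912 RPKM (7.12 ± 0.8), with rises of 6.97 ± 0.71, 6.23 ± 0.71 and 6.09 ± 0.7 for SVEN15_6649, SVEN15_6647 and SVEN15_6644. Without mtrB::apr 14 h replicate 1 the rises of SVEN15_6645 and SVEN15_6649 were 7.98 and 6.31, and without replicate 2 they were 6.26 and 7.63. WhiD (SVEN15_4354) rose by 5.28 ± 0.46, from 52.9 to 2110 RPKM. The list of developmental regulators had 2 of 14 higher and 3 lower (3 and 3 adjusted over the list alone). It was not called (camera adjusted p = 0.759; fry adjusted p = 0.224). Ribosomal protein genes fell, 34 of 58 with 1 higher (41 and 1 adjusted over the list alone; median -0.96; camera adjusted p = 1.63e-11; adjusted p = 0.406 with an estimated correlation). L22p (SVEN15_4287) fell by 1.64 ± 0.23, while L31p (SVEN15_7163) rose by 5.17 ± 0.72. ATP synthase genes fell, 6 of 10 (7 adjusted over the list alone; median -0.88; camera adjusted p = 0.000533; adjusted p = 0.406 with an estimated correlation). SVEN15_4916 fell by 1.11 and SVEN15_4918 fell by 1.07, both not called without mtrB::apr 20 h replicate 1 (adjusted p = 0.0529 and 0.0648). NADH dehydrogenase genes were lower as a list (median -0.44 over 25 genes; camera adjusted p = 0.000984; adjusted p = 0.579 with an estimated correlation; fry adjusted p = 0.073), and not without mtrB::apr 14 h replicate 1 (0.116). Its called member was chain B (SVEN15_4171, -0.66, adjusted p = 0.0409), and its call was lost without each library outside WT 20 h (0.0663 to 0.227), with the replicate block (0.0501), with only the 4 libraries compared (0.0778) and without the trend (0.064). Gas vesicle genes rose, 8 of 16 (9 adjusted over the list alone; median 1.15; camera adjusted p = 0.00448; adjusted p = 0.579 with an estimated correlation). SVEN15_6707 rose by 1.71, SVEN15_6709 by 1.82 and SVEN15_6705 by 2.46 ± 0.56, the last not called without mtrB::apr 14 h replicate 1 or either mtrB::apr 20 h library (adjusted p = 0.061 to 0.0691). That rise was 1.71 without mtrB::apr 14 h replicate 1 and 3.21 without replicate 2. Phosphate uptake genes had 8 of 16 higher and 2 lower (10 and 2 adjusted over the list alone; median 1.31; camera adjusted p = 0.0293; adjusted p = 0.579 with an estimated correlation), not called as a list without mtrB::apr 20 h replicate 1 (0.0527). PstA (SVEN15_3806) and PstB (SVEN15_3805) of the phosphate transporter rose by 4.39 ± 0.72 and 3.91 ± 0.58 and an alkaline phosphatase (SVEN15_0829) by 2.81 ± 0.32. The mtrB::apr 14 h replicates stood apart for PstA (149 and 19.4 RPKM) and PstB (237 and 48.5 RPKM), so the rises were 5.83 and 5.04 without replicate 1 and 2.95 and 2.77 without replicate 2. The lower ones were a low-affinity phosphate transporter (SVEN15_1451, -2.54 ± 0.29) and UgpC (SVEN15_3884, -0.72, adjusted p = 0.0458), which was chosen after its values were seen and lost its call without each library outside WT 20 h except mtrB::apr 14 h replicate 2 (0.118 to 0.222). The call of UgpC also ended with the replicate block (0.0531), with only the 4 libraries compared (0.0744) and without the trend (0.0606).

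Heat shock and chaperone genes in the mutant had 5 of 18 lower and 2 higher with time (median -0.46; camera adjusted p = 0.0321; adjusted p = 0.406 with an estimated correlation; 0.116 without mtrB::apr 20 h replicate 1). Lower were ClpB (SVEN15_3348, -1.54 ± 0.25), DnaK (SVEN15_3357, -1.11 ± 0.21) and, chosen after their values were seen, GroEL (SVEN15_3957, -1.08; SVEN15_4343, -0.84) and GroES (SVEN15_4342, -0.96). Those 3 lost their call without mtrB::apr 14 h replicate 1 or either mtrB::apr 20 h library (adjusted p = 0.0502 to 0.205), and SVEN15_4342 and SVEN15_4343 without either WT 14 h library (0.0621 to 0.0805). Higher were HspR (SVEN15_3391, 1.34 ± 0.22), the repressor of the dnaK operon, and the copper chaperone SVEN15_2478 (1.26 ± 0.26, adjusted p = 0.00612; 0.0549 without mtrB::apr 20 h replicate 2). Outside the lists, the fructose genes SVEN15_2988, SVEN15_2989 and SVEN15_2990 fell (-7.15, -7.21 and -7.46), as did the glutamate uptake run SVEN15_5319 to SVEN15_5322 (-5.99, -6.03, -5.61 and -5.6) and the branched-chain keto acid dehydrogenase genes SVEN15_3520, SVEN15_3521 and SVEN15_3522 (-4.96, -5.86 and -5.99). Without mtrB::apr 14 h replicate 1 the changes of SVEN15_3520, SVEN15_3521 and SVEN15_5322 were -5.74, -6.59 and -5, and without replicate 2 they were -4.18, -5.13 and -6.2. That of SVEN15_2990 was -6.67 without mtrB::apr 20 h replicate 1 and -8.25 without replicate 2. A hydrolase gene (SVEN15_1880) rose by 6.23 ± 0.39, 3-isopropylmalate dehydrogenase (SVEN15_5098) by 5.89 ± 0.3 and the hemolysin SVEN15_6718 by 5.83 ± 0.38. The count was 1952 of 7233 genes, 1273 higher (65.2%) and 679 lower. With quantile normalisation it was 2196, 46% of them higher, and the median over all genes was -0.16 instead of 0.08. Without mtrB::apr 20 h replicate 1 or 2 the count was 988 or 961.

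**Figure D3:**
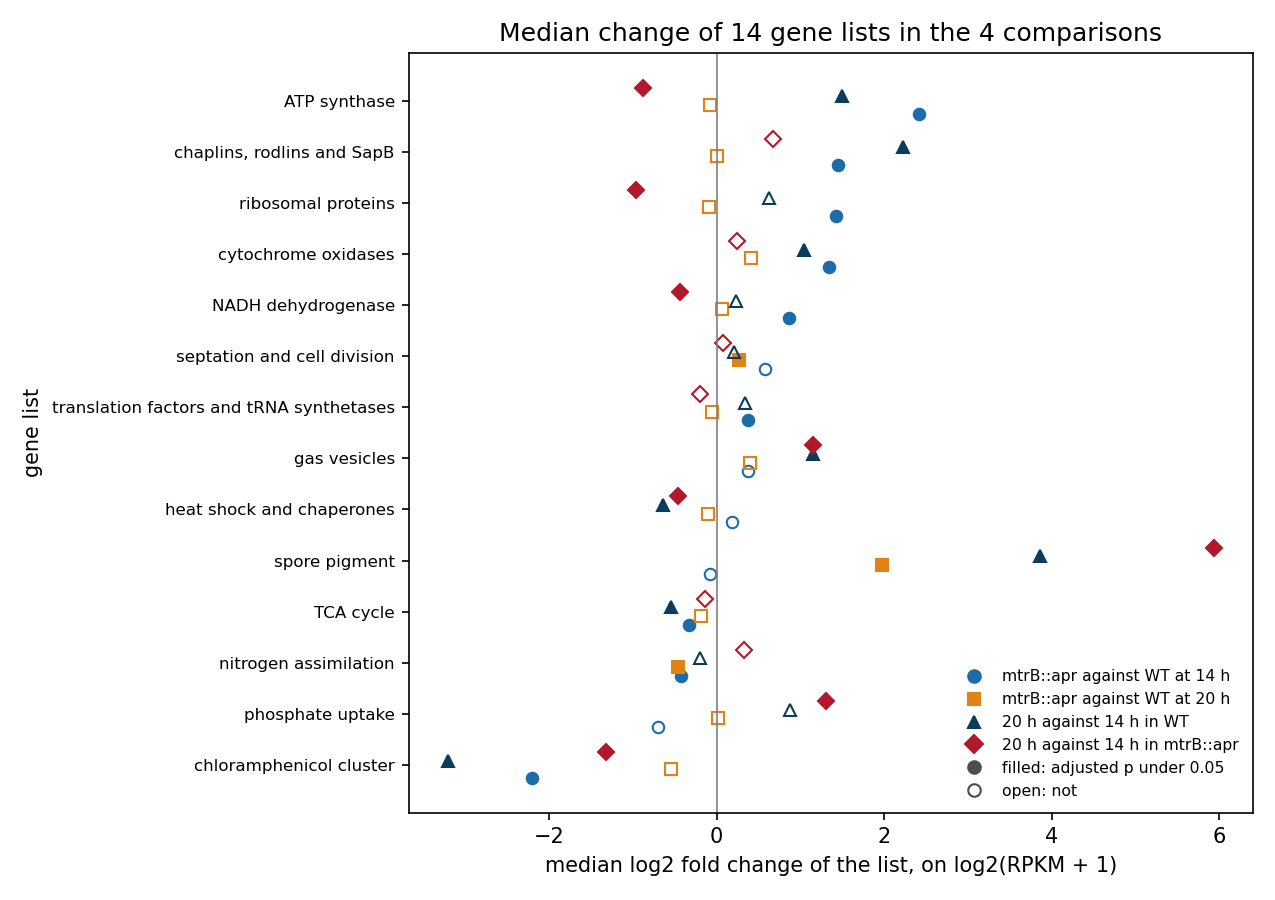
Median log2 fold change over the measured genes of the 14 gene lists called in at least 1 of the 4 comparisons, with a symbol per comparison, filled where the camera adjusted p is under 0.05 and open where not. Ribosomal protein genes lie at 1.42 in mtrB::apr against WT at 14 h and at -0.96 in the mutant with time, and the chloramphenicol list lies at -2.2 and -1.32.

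The effect of the mutation was not alike at both times. Across genes, which are not independent replicates, the log2 fold changes at 14 h and 20 h had Pearson's r = 0.21 and Spearman's rho = 0.25, and r was 0.1 to 0.24 over the 16 choices of 1 library per group. Of the genes called at both times 9 were higher at both (4.94 if the lists were independent), 14 lower at both (3.18), 3 higher at 14 h and lower at 20 h (3.82; SVEN15_1838, SVEN15_3526 and SVEN15_6339) and 4 the other way (4.11; SVEN15_2610, SVEN15_5136, SVEN15_5230 and SVEN15_6746). A test of the difference called 521 genes, 241 of which (46.3%) had a higher effect at 20 h. With median-ratio scaling it called 510, 68% of them with a higher effect, and the median over all genes was 0.06 instead of -0.21. The count was 128 or 120 without WT 14 h replicate 1 or 2, 1056 without WT 20 h replicate 1, and 132 or 172 without mtrB::apr 20 h replicate 1 or 2. The changes with time in WT and in the mutant had r = 0.67 and rho = 0.61 across genes (r 0.55 to 0.69 with 1 library per group), with 943 genes higher in both (367 if independent), 296 lower in both (76.6), 45 higher in WT and lower in the mutant (196) and 54 the other way (144). The mutant effect at 14 h and the change of WT with time had r = 0.63 and rho = 0.62, with 553 genes higher in both (234 if independent), 471 lower in both (76.3), 20 higher in the mutant and lower with time (91.6) and 23 the other way (195). Both use the WT 14 h libraries, so independence is no fair base for these counts. Unchanged groups of equal scatter give an r near 0.5 by construction (mean 0.499 in 100 simulations, highest 0.526). That r therefore does not say how much of 0.63 comes from the sharing. The covariance of the 2 effects was 0.743, against a mean of 0.0565 in the same simulations. In the authors' deposited comparison tables, 1717 genes had a false discovery rate under 0.05 at 14 h (1419 of them also called here), 273 at 20 h (78), 2936 for WT with time (2724) and 2027 for the mutant with time (1830). Every shared call had the same sign.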

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

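All tests of explanations in this part were chosen after the results were seen. The patterns below were found and tested on the same data.

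The effect of the mutation differed between 14 h and 20 h by a test of the difference itself (effect at 20 h minus effect at 14 h, log2). Lower effects at 20 h were found for genes annotated for phenylacetate breakdown, not tested as a group: SVEN15_3526 by -6.38, SVEN15_3532 by -6.81, SVEN15_3533 by -6.82 and SVEN15_3534 by -7.92. The keto acid dehydrogenase gene SVEN15_3521 also had a lower effect (-6.16, adjusted p = 0.0141), whose call was lost without either WT 14 h library (0.0529 and 0.0522), mtrB::apr 14 h replicate 2 (0.0524) or either mtrB::apr 20 h library (0.0694 and 0.0624). Leaving out a library moved these values, for SVEN15_3521 from -7.74 (without WT 20 h replicate 2) to -4.57 (without replicate 1), and for SVEN15_3532, SVEN15_3533 and SVEN15_3534 from -8.77 (SVEN15_3534 without mtrB::apr 14 h replicate 1) to -6.02 (SVEN15_3533 without replicate 2). Higher effects at 20 h were found for SVEN15_3830 by 6.15, SVEN15_3831 by 6, SVEN15_5794 by 5.61 and SVEN15_5795 by 5.56, and the reductase gene SVEN15_5874 by 6.1. Most of each difference came from the fall in the mutant at 14 h (-5.65 to -4.53), since the effects at 20 h were 0.46 to 1.19. Among the lists, the median difference was -2.08 for ATP synthase (camera adjusted p = 9.61e-09), -1.56 for the rodlins (0.0205), -0.78 for the cytochrome oxidases (0.00851), -0.57 for NADH dehydrogenase (0.00175), -1.54 for ribosomal proteins (2.19e-16) and -0.48 for translation factors and tRNA synthetases (0.00835). It was 2.02 for the chloramphenicol list (2.82e-09), 1.69 for the spore pigment (0.00818, with no member called) and 0.32 for the TCA cycle (0.00315). With median-ratio scaling the medians were -0.5 for the cytochrome oxidases, -0.29 for NADH dehydrogenase, -0.2 for translation factors and 0.6 for the TCA cycle. With an estimated correlation no list passed for the difference (adjusted p = 0.141 to 0.405 for these lists), and by fry the spore pigment (0.357), chloramphenicol (0.0729) and cytochrome oxidase (0.0641) lists did not. The spore pigment list was not called without WT 20 h replicate 2 (median 0.4, adjusted p = 0.137) and had a median of 3.1 without replicate 1, so its size and its call depend on the WT 20 h replicates. The rodlins and the cytochrome oxidases were not called without WT 20 h replicate 1 (0.0755 each) or mtrB::apr 14 h replicate 1 (0.0869 and 0.0558), NADH dehydrogenase without the latter (0.0558), and the TCA cycle without mtrB::apr 14 h replicate 2 (median 0.13, adjusted p = 0.0653). Without mtrB::apr 14 h replicate 1 the chloramphenicol median was 1.18, and the TCA median was 0.5 without it and 0.55 without WT 20 h replicate 1.

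The first pattern weighed is the near loss of SVEN15_3350 and SVEN15_3351 in mtrB::apr at both times: the mutant kept 1.79% and 1.34% of the WT level at 14 h and 2.07% and 1.37% at 20 h, against 1.4% and 1.74% for the disrupted mtrB. A lost stretch of chromosome that reaches the neighbouring genes is argued against, since the lowest log2 fold change of SVEN15_3349 and SVEN15_3352 at either time was 0.22. Carry-over from the WT 14 h libraries into those of mtrB::apr 20 h is argued against, since both genes kept at least 8.86 times the share (1.86% and 2.71% of WT 14 h) that was seen for the 3 lowest other genes (SVEN15_2989, SVEN15_2990 and SVEN15_5724, 0.12% to 0.21%). That ratio is rough, since those 3 genes had only 2.43 to 3.85 read equivalents in their lower mtrB::apr 20 h library, near the floor of 3 reads. Carry-over from the WT libraries of the same time cannot be told apart from a strong fall in transcription. The lowest ratio of the share left of SVEN15_3350 and SVEN15_3351 to that of mtrB was 0.788 and the highest 1.28. A deletion of these genes alone, another change in the strain and an effect of the kinase stay open, untested.

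The second pattern is the higher spore pigment list in mtrB::apr at 20 h (median 1.98). Low values in WT 20 h replicate 2 alone are not settled as its source: without that library the median was 0.57 and the adjusted p 0.0122, and in 9 of 10 genes both mutant libraries lay above WT replicate 1. Most of these genes lie in a single run (SVEN15_6644 to SVEN15_6651), and the estimated correlation of the list was 0.441. The 9 genes are thus not separate observations. A candidate explanation for part of the size is that WT 20 h replicate 2 was less far along the change from 14 h to 20 h than replicate 1, since replicate 2 minus replicate 1 had r = -0.33 across genes with the change of the mutant with time, which shares no library with it. Whether the strain adds to this stays open with a single WT library left.

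The third pattern is that the mutant effect at 14 h goes along the change of WT from 14 h to 20 h. Scatter between replicates in the shared WT 14 h libraries is argued against as its whole source. The covariance of both effects was 0.743, against at most 0.0614 in simulations of unchanged groups. These simulations hold only scatter between replicates. A departure common to both WT 14 h libraries would enter both effects and was not tested. Progress of the mutant by the same share of the WT change in every gene is also argued against, for the spore pigment genes. The fitted share was 0.47, which predicts 1.81 for the spore pigment median at 14 h, and the observed median was -0.08 (SD of members 0.49). The test takes each gene to move by that share. It cannot weigh an earlier progress in which the spore pigment genes have yet to rise at 14 h. The SD is the spread of the members and not an error of the prediction, which rests on WT 20 h replicates that stood apart. An equal share would keep each list's median smaller than in WT with time. At 14 h it was larger for ATP synthase (2.42 against 1.5), ribosomal proteins (1.42 against 0.63) and NADH dehydrogenase (0.87 against 0.23). Cytochrome oxidases (1.34 against 1.04) and translation (0.38 against 0.34) went that way. Nitrogen genes fell more (-0.42 against -0.2), chloramphenicol (-2.2 against -3.21) and TCA genes (-0.33 against -0.55) less. Rodlins rose less (1.45 against 2.23). An advance of only some of the genes, or a separate effect of the kinase on them, was not tested.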

How the results depend on the processing

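Left-out libraries and the estimated correlation changed the counts most, and the alternatives that left a library out of the correlations or changed list members were chosen after seeing the data. The counts of called genes, with the range over libraries left out, were 1488 (478 to 1988) at 14 h, 78 (6 to 682) at 20 h, 2901 (1500 to 3195) for WT with time, 1952 (961 to 2384) for the mutant with time and 521 (120 to 1056) for the difference. A WT 14 h library is in no contrast of 20 h, yet without it the pooled spread loses its tightest pair and the count at 20 h was 27. The count at 20 h was 51 with a pseudocount of 0.1 and 18 with only the 4 libraries compared. For the difference, where all alternatives for lists were added after seeing the data, 9 lists were called, 7 to 9 over libraries left out, 10 by fry and 0 with an estimated correlation. The list counts were 9 at 14 h, 3 at 20 h (1 to 5 over libraries left out), 8 and 8, each 0 with an estimated correlation, and 15, 1 and 16 by fry at 14 h, 20 h and for WT with time. The correlation of mutant effects, 0.21, was 0.16 to 0.25 over libraries left out (0.16 without mtrB::apr 14 h replicate 1, 0.17 without WT 20 h replicate 2), and that of time effects, 0.67, was 0.6 (without WT 20 h replicate 1) to 0.7. With a replicate block, the counts were 1570, 96, 2956, 2044 and 549. Of 3787 alternative values for the named genes, 7 reversed sign, all in genes not called: SVEN15_3971 at 14 h (0.05) was -0.11 with median-ratio scaling and -0.02 to 0.12 over libraries left out (lowest without WT 14 h replicate 1), and with time in WT (-0.02) it was 0.05 and 0.08 without WT 14 h replicate 2 and WT 20 h replicate 1. SVEN15_0880 with time in the mutant (0.14) was -0.05 with quantile normalisation, -0.25 to 0.54 over libraries left out, lowest without mtrB::apr 14 h replicate 1, and -0.03 without mtrB::apr 20 h replicate 2. A further 290 ended a call, 202 with a library left out and 88 with other settings (29 with only the 4 libraries compared, 12 without the trend, 11 with a pseudocount of 0.1, 9 with quantile normalisation, 6 with median-ratio scaling, 3 with the replicate block). Of 186 called pairs of a named gene and a comparison, those called without each library in turn were 49 of 64 at 14 h, 4 of 31 at 20 h, 37 of 39 for WT with time, 30 of 40 for the mutant with time and 10 of 12 for the difference. Except where stated, the cause was not tested. On simulated data with 200 changed genes and a single dispersion, 15% to 27% of changes of 2-fold were recovered (7% in the difference), which need not hold at the spread and number of changes seen here. Since the files hold no counts, edgeR and DESeq2 were not run.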

Other observations

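Further single genes fell in the mutant at 14 h. They were chosen after their values were seen, and no list of sulfate or histidine genes was tested. A sulfate transporter permease gene (SVEN15_5789) went from 260 ± 20.3 RPKM in WT to 11.6 ± 0.729 RPKM in mtrB::apr, a log2 fold change of -4.37 ± 0.26 (adjusted p = 1.02e-05). Sulfite reductase (SVEN15_5798) went from 271 ± 12.3 to 14.6 ± 2.58 RPKM (-4.13 ± 0.25, adjusted p = 1.14e-05). Both were low at 20 h in WT too, at 20 ± 1.23 and 24.5 ± 0.876 RPKM. Histidine ammonia-lyase (SVEN15_4503), the first enzyme of histidine breakdown, fell by 4.26 ± 0.33 at 14 h. The activating enzyme gene of pyruvate formate-lyase (SVEN15_2978) rose by 1.94 ± 0.31 at 14 h already (adjusted p = 0.00234).

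Of 14 developmental regulators, 3 were higher and 1 lower at 14 h (6 and 2 adjusted over the list alone). The list was not called (camera adjusted p = 0.331; fry adjusted p = 0.00985). The called genes were WhiB (SVEN15_2717, 1.26, adjusted p = 0.0192), WhiB family regulators (SVEN15_4802, 1.04, adjusted p = 0.0124; SVEN15_2793, 1.84, adjusted p = 0.04) and BldB (SVEN15_5272, -0.83, adjusted p = 0.0397). These calls were lost without either WT 14 h library (adjusted p = 0.0588 to 0.258) and without mtrB::apr 14 h replicate 1 (0.0519 to 0.215). Those of SVEN15_2793 and BldB were also lost without either mtrB::apr 20 h library (0.0653 to 0.066), and the change of SVEN15_2793 was 1.18 without mtrB::apr 14 h replicate 1 and 2.49 without replicate 2. Median-ratio scaling ended the calls of SVEN15_2717 (0.0537) and SVEN15_2793 (0.0532), and quantile normalisation those of SVEN15_4802 (0.137), SVEN15_2793 (0.0914) and BldB (0.081). That of SVEN15_2793 also ended with a pseudocount of 5 (0.0863) and with only the 4 libraries compared (0.0677), and that of BldB without the trend (0.0554). The change of SVEN15_2793 is taken near the floor, with 1 and 0 RPKM in the WT 14 h libraries and 6.95 and 2.21 RPKM in those of mtrB::apr. WhiD (SVEN15_4354) changed by -0.41 ± 0.46 (adjusted p = 0.563).

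Genes with opposite effects at the 2 times were chosen after their values were seen. The repressor MalR (SVEN15_1838) was higher in the mutant at 14 h (3.23) and lower at 20 h (-1.59), and so were PaaZ (SVEN15_3526, 4.71 and -1.67) and SVEN15_6339 of unknown function (1.16 and -1.51). Lower at 14 h and higher at 20 h were SVEN15_2610 (annotated as Mec+, -1.07 and 1.32), 3-isopropylmalate dehydratase (SVEN15_5136, -1.02 and 1.51), a gamma-aminobutyrate aminotransferase (SVEN15_5230, -1.52 and 1.57) and mannose-6-phosphate isomerase (SVEN15_6746, -3.31 and 1.88). Without either mtrB::apr 20 h library, each of the 20 h calls was lost (adjusted p = 0.103 to 0.408). All of them but SVEN15_6746 were also lost without either WT 14 h library (0.0767 to 0.125), and those of SVEN15_1838, SVEN15_6339 and SVEN15_5136 without WT 20 h replicate 2 (0.101 to 0.136). At 14 h, SVEN15_6339, SVEN15_2610 and SVEN15_5136 lost their call without either WT 14 h library (0.0971 to 0.248), SVEN15_6339 and SVEN15_5136 without mtrB::apr 14 h replicate 2 (0.0814 and 0.11, with changes of 0.77 and -0.65) and SVEN15_5136 without either mtrB::apr 20 h library (0.0649 and 0.0648). The 14 h call of SVEN15_5136 also ended with quantile normalisation (0.0619) and only the 4 libraries compared (0.0688). At 20 h the replicate block ended the call of SVEN15_6339 (0.052), and with only the 4 libraries compared all 7 calls ended (0.0715 to 0.135). Those of SVEN15_1838, SVEN15_3526, SVEN15_6339 and SVEN15_5136 ended with a pseudocount of 0.1 (0.0508 to 0.0577) and without the trend (0.0568 to 0.0643). Robust moderation (0.0519 and 0.0516) and no filter (0.0501 each) ended those of SVEN15_1838 and SVEN15_6339, and quantile normalisation that of SVEN15_5136 (0.055).

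In none of the 4 comparisons of groups were 10 of the 24 lists called by camera. Their lowest adjusted p by camera was 0.331 for developmental regulators, 0.5 for cell wall hydrolases, 0.268 for cell wall synthesis, 0.164 for DNA replication, 0.141 for iron transport and 0.349 for the mtrA operon. It was 0.263 for other specialised metabolism, 0.0606 for oxidative stress, 0.263 for sigma and anti-sigma factors and 0.494 for sensor kinases and response regulators. By fry all of them passed in at least 1 comparison, except cell wall hydrolases and the sensor kinases and response regulators. Fry was run on values as deposited and does not allow for a shift of all genes, whose median was 0.39 for WT with time. Iron transport and the sigma factors passed by fry only there (0.0459 each). Their medians of 0.24 and 0.15 were -0.08 and -0.19 with median-ratio scaling. At 14 h the fry adjusted p was 0.00273 for oxidative stress and 0.00827 for cell wall synthesis. At 20 h only the mtrA operon passed by fry (0.00387).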
